A study of Exaiptasia diaphana with 6 samples.

How the data were processed

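Polyadenylated RNA was measured in 6 small pools of endodermal cells from larvae of the sea anemone Exaiptasia diaphana (Aiptasia), a laboratory model for the symbiosis between cnidarians and algae. Per the labels, the larvae were 5 days post fertilization when exposure to the microalga Microchloropsis gaditana began, exposure lasted 48 h, and sampling took place at 7 days; the series design text gives 24 to 48 h after uptake. The ectoderm was removed, the endoderm was macerated and single cells were collected with a microcapillary. Per the labels' protocols, libraries were made with SmartSeq2, a full-length method for very small RNA inputs, using 21 PCR cycles of cDNA amplification and 75 bp paired-end sequencing. The protocols name no molecular identifiers.

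The labels define 2 groups of 3 libraries, and all cells came from larvae exposed to the alga. The aposymbiotic group (Mg-Apo) held cells without an alga, with 10, 16 and 15 cells in replicates 1, 2 and 3. The alga-containing group (Mg) held 2 alga-containing cells and 1 aposymbiotic cell in replicate 1, 3 alga-containing cells and 1 aposymbiotic cell in replicate 2, and 4 alga-containing cells in replicate 3. Group and cell number are thus confounded. The labels do not say whether replicates came from separate larvae or cultures, so p-values measure the spread between these libraries, which may in part be technical.

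The deposited table holds a TMM-normalized abundance signal for 27334 RefSeq transcripts, of which 26087 carry coding (XM) and 1247 non-coding (XR) accessions. The submitters' processing notes name HISAT2 2.1.0, Salmon 0.10.2 and DESeq2 without assigning them roles, and the genome build is not given in the sources used here. TMM is a scaling between libraries that assumes that most transcripts do not change. Whether the authors scaled TPM, CPM or another abundance is not stated; the columns sum to between 728347 and 1257179, so they are neither TPM nor CPM as such. Of the values above 0, 99.9% are not whole numbers, reads were not recovered from them, and the sequencing depth behind each value is unknown. No counting interval or detection floor was therefore computed, and tests of read counts were not applicable. A value of 0 is described as listed at 0, since it can be an estimate that failed.

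Columns were assigned to samples by matching their names to the sample titles. Of the 27334 accessions, 2683 matched the RefSeq gene table of Aiptasia genome 1.1 with their version and 21267 (77.8%) without it, in 18293 genes, 1953 of which had more than 1 transcript in the deposited table; 6067 accessions did not match. Matched genes carry LOC identifiers, with 1 exception, Chrna7, and the gene table used here gives no product names. The 24 gene lists fixed before the data were examined (immune signalling, pattern recognition receptors and lectins, complement, lysosome, V-type ATPase, endosomal traffic, actin, MAP kinases, oxidative stress, chaperones, apoptosis, autophagy, lipid transport, nutrient transport, glycolysis, respiration, ribosome, proteasome, cell cycle, markers of cnidocytes, neurons, gland cells and muscle, and algal photosynthesis) therefore matched 0 genes each, and the planned gene list tests were not run. Gene functions are not reported for the same reason.

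The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(value + 1), Mg against Mg-Apo, without covariates. It covered the 8401 transcripts with a value of at least 1 in at least 3 of the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fitted changes are on the log2(value + 1) scale, which understates the change of transcripts with low values. The rule for naming, fixed before the data were examined, fell back on identifiers because too few of the tested genes had a name: the 2 transcripts with the smallest p in each direction and the 5 with the highest mean over the 6 libraries are given. Group differences in library measures were tested with two-sided exact permutation tests, which cannot go below p = 0.10 with 3 libraries against 3. Transcripts above 0 in exactly 3 libraries were compared with a conditional model that gives each library a single odds of detection (NumPy 2.4.6, SciPy 1.17.1).

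The limma code was tested on simulated data for the same comparison and the same 8401 transcripts. With normal values of SD 0.5, it recovered 95% of 100 transcripts changed 4-fold and 100% of 100 changed 64-fold, with 13 false calls. With the real values shuffled within each transcript, it recovered 1% of those changed 4-fold and 22% of those changed 64-fold, with 1 false call. In that simulation values of 0 stayed at 0 when multiplied. The median fitted change was 1.54 log2 units for the 4-fold and 5.09 for the 64-fold transcripts. The detection model gave a ratio of observed to expected of 0.98 for the Mg libraries in simulated data of 8000 transcripts without group-specific transcripts and 1.64 when 200 Mg-specific ones were added. Sets of 3 libraries that mixed the groups had ratios of 0.61 to 1.27 without the added transcripts and 0.49 to 1.20 with them.

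Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a minimum of 10, detection in all 6 libraries, quantile normalization, centring on library medians, 3 other variance or weight settings, a replicate block, leaving out each library, and leaving out both Mg libraries that held an aposymbiotic cell. The centring used medians over the transcripts above 0 in all 6 libraries.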

Results

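Gene expression was compared between endodermal cells of Aiptasia larvae that contained the microalga M. gaditana and aposymbiotic cells from exposed larvae. M. gaditana is a marine microalga that is not a native symbiont of this host, and the comparison asks how a host cell's transcripts differ when it holds such an alga. There were 3 libraries with alga-containing cells (Mg) and 3 of aposymbiotic cells (Mg-Apo). Mg 1 and Mg 2 also held 1 aposymbiotic cell each. The total normalized signal was 728347, 1084622 and 1091026 in Mg-Apo 1, 2 and 3, and 1257179, 1019472 and 1035734 in Mg 1, 2 and 3. Of the 27334 transcripts in the deposited table, 18293 were above 0 in at least 1 library, 2288 were above 0 in all 6 and 9041 were listed at 0 in all 6.

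More transcripts were detected in the Mg libraries on average, but the difference was within the spread between libraries. The Mg libraries had 13674, 9771 and 9909 transcripts above 0, with a mean of 11118 ± 2215 (SD, n = 3). The Mg-Apo libraries had 4660, 9241 and 10139, with a mean of 8013 ± 2939 (SD, n = 3). The difference of 3105 transcripts had a two-sided exact permutation p = 0.3, where 0.10 is the smallest p that this design allows. Mg-Apo 1 stood apart: 55.9% of the tested transcripts were listed at 0 in it, against 21.9% and 15.8% in the other Mg-Apo libraries and 5.61%, 18.3% and 18.9% in the Mg libraries. Without Mg-Apo 1 the difference was 1428 transcripts (exact permutation p = 0.7), and without Mg 1 it was 1827 (exact permutation p = 0.7). Without each of the other 4 libraries it lay between 3709 and 4168, with exact permutation p from 0.1, without Mg-Apo 3, to 0.4; 0.1 is also the smallest p for 2 libraries against 3. Within Mg-Apo, the library with the fewest cells, 10, had the fewest transcripts above 0, while within Mg the library with the fewest cells, 2 with an alga and 1 without, had the most. Cell number and group cannot be separated in this design, because every Mg-Apo library pooled more cells than every Mg library.

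**Figure D1:**
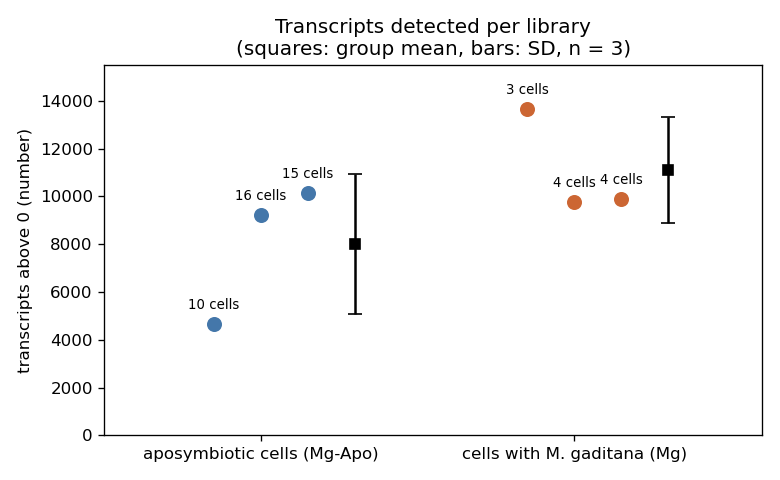
Number of transcripts above 0 in each library (vertical axis) for the Mg-Apo and Mg groups; circles are libraries marked with the number of cells pooled, squares are group means and bars are SD (n = 3). Mg-Apo 1 has 4660 transcripts, Mg 1 has 13674, and the other 4 libraries lie between 9241 and 10139.

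The Mg and Mg-Apo libraries shared most of their abundant transcripts. Of the 100 transcripts with the highest mean in Mg, 87 were also among the 100 highest in Mg-Apo. The overlap between libraries of the same group was not computed for comparison. The 100 with the highest overall mean were above 0 in all 6 libraries, which their choice by that mean favours. The transcript with the highest mean was XR_002334655.1 (gene LOC110239353, annotated as a long non-coding RNA), at 66448 ± 11004 in Mg and 57962 ± 10495 in Mg-Apo (SD, n = 3 each; exact permutation p = 0.4), which was 6.13% of the signal on average. Next came the protein-coding transcript XM_021060755.1 (LOC110253803), at 57381 ± 15661 in Mg and 54658 ± 14870 in Mg-Apo (SD, n = 3 each; exact permutation p = 1.0). XM_021046698.1 (LOC110240879) had 21779 ± 4083 and 22186 ± 2028 in Mg and Mg-Apo, XM_021053441.1 (LOC110247057) had 15829 ± 5419 and 16041 ± 3991, and XM_021040805.1 (LOC110235349) had 12126 ± 1205 and 10528 ± 2801 (SD, n = 3 each); the exact permutation p-values were 1.0, 1.0 and 0.7. Together these 5 transcripts held 15.8% ± 2.43 of the signal in Mg and 17.0% ± 2.48 in Mg-Apo (SD, n = 3 each; exact permutation p = 0.5). Non-coding accessions held 11.6% ± 1.21 of the signal in Mg and 11.1% ± 1.77 in Mg-Apo (SD, n = 3 each; exact permutation p = 0.9). None of these 7 p-values reached the smallest value of 0.10 that this design allows, and each was 1.0 after Benjamini-Hochberg adjustment over the 7.

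Libraries of the same group were not measurably more alike than libraries from different groups. Over the 8401 tested transcripts, the mean Pearson correlation of log2(value + 1) was 0.42 within groups (6 pairs, 0.36 to 0.50) and 0.43 between groups (9 pairs, 0.34 to 0.52). These correlations are across transcripts, which are not independent replicates. The difference of -0.0062 was matched or exceeded by 6 of the 10 splits of the 6 libraries into 3 and 3 (one-sided exact permutation p = 0.6). Without Mg-Apo 1, the mean was 0.45 within and 0.46 between groups.

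No transcript passed the test between the Mg and Mg-Apo libraries. Of 8401 transcripts tested with limma, 0 were higher and 0 lower in Mg at an adjusted p under 0.05, and the lowest adjusted p was 0.54. At an unadjusted p under 0.05 there were 503 transcripts, where 420 are expected by chance; 459 of them were higher and 44 lower in Mg. The fitted changes of all tested transcripts were shifted upwards, with a median of 0.76 on the log2(value + 1) scale and 68.7% above 0. The median was 1.29 with a pseudocount of 0.1, 0.41 with a pseudocount of 5, 0.49 with library weights and 0.16 for the transcripts above 0 in all 6 libraries. The median was 0.15 without Mg-Apo 1, 0.55 without Mg 1 and between 0.83 and 1.01 without each of the other 4 libraries. Without Mg-Apo 1 there were 324 higher and 88 lower transcripts at an unadjusted p under 0.05. The median was -0.00095 without both Mg-Apo 1 and Mg 1, an exclusion chosen after seeing the data, which left 276 higher and 323 lower transcripts at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05. Without Mg 3, 401 were higher and 29 lower at an unadjusted p under 0.05. Centring on the library medians of the transcripts above 0 in all 6 libraries gave a median of 0.65, with 448 higher and 56 lower. Those medians leave out every transcript listed at 0 in any library. Quantile normalization, which brings the medians of the libraries together by construction, gave -0.03, with 252 higher and 172 lower. Splits into 3 and 3 that mixed the groups gave medians of 0.24 to 0.89, as libraries without Mg-Apo 1 minus those with it. The values of the Mg libraries lay all above those of the Mg-Apo libraries for 739 transcripts and all below for 132. Together these were 10.4% of those tested, where chance gives 10% for 3 libraries against 3 in both directions together. The directions were far from equal, as they were at an unadjusted p under 0.05.

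**Figure D2:**
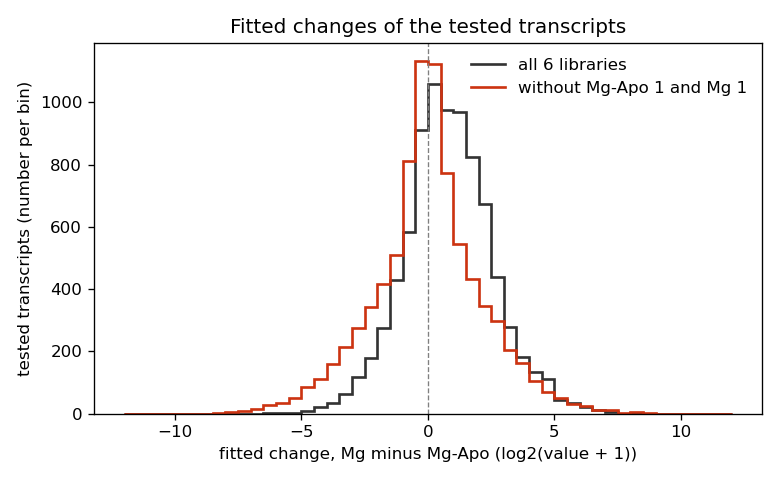
Distribution of the fitted change between Mg and Mg-Apo (horizontal axis, log2(value + 1)) over the 8401 tested transcripts (vertical axis, number per bin of 0.5), for all 6 libraries and without Mg-Apo 1 and Mg 1. The median is 0.76 with all 6 libraries and -0.00095 without those 2.

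The spread between libraries set a wide limit on what could be detected. The median SD of log2(value + 1) between replicates was 1.54 in Mg and 2.26 in Mg-Apo, and 73.5% of the tested transcripts were listed at 0 in at least 1 library. The 95% interval of a fitted change reached 3.98 log2 units to either side in the median transcript. For the 2227 tested transcripts above 0 in all 6 libraries, the median SD was 0.84 in Mg and 0.99 in Mg-Apo. A test of the 2288 transcripts above 0 in all 6 libraries, with no minimum value, gave 0 calls with limma and 97 at an unadjusted p under 0.05, against 114 expected by chance. When the values were shuffled and transcripts then changed by a known fold, limma called 1% of those changed 4-fold and 22% of those changed 64-fold. Multiplying left values of 0 at 0, so these shares also reflect the zeros and not the spread alone.

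The 2 transcripts with the smallest unadjusted p in each direction were near 0 in the libraries of one group and well above it in the other, and none passed the adjusted threshold. XM_021053286.1 (LOC110246903, protein coding) was at 218, 425 and 575 in Mg 1, 2 and 3, and at 0, 0 and 0.528 in Mg-Apo 1, 2 and 3; its fitted change was 8.36 ± 1.46 (SE), with a limma adjusted p = 0.54. XM_021055704.1, which did not match the gene table, was at 411, 190 and 549 in Mg and listed at 0 in the Mg-Apo libraries, with a limma adjusted p = 0.54. In the other direction, XM_021050820.1 (LOC110244615, protein coding) was at 131, 216 and 40.3 in Mg-Apo 1, 2 and 3, and at 1.58, 0 and 0 in Mg 1, 2 and 3, a fitted change of -6.27 ± 1.69 (SE) with a limma adjusted p = 0.54. XM_021040178.1 (LOC110234783, protein coding) was at 138, 49.5 and 45.3 in Mg-Apo and at 0.318, 0 and 0 in Mg, a fitted change of -5.97 ± 1.67 (SE) with a limma adjusted p = 0.54. These fitted changes depend on the pseudocount, because one group is near 0. With pseudocounts of 5 and 0.1 they were 6.21 and 10.99 for XM_021053286.1, -4.34 and -8.67 for XM_021050820.1, and -3.84 and -8.72 for XM_021040178.1. The single gene with a symbol other than a LOC identifier, Chrna7, was listed at 0 in all 6 libraries.

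More transcripts were restricted to the alga-containing libraries than to the aposymbiotic ones. In total 375 transcripts were above 0 in all 3 Mg libraries and listed at 0 in all 3 Mg-Apo libraries, and 6 showed the reverse. Sets of 3 libraries that mixed the groups held between 19 and 404 such transcripts, and 2 of these 18 sets held at least as many as the Mg set. The count for Mg-Apo changed most without Mg-Apo 1. Then 163 transcripts were above 0 in both other Mg-Apo libraries and listed at 0 in Mg, against 472 the other way. The Mg count was 546 without Mg 1, 730 without Mg-Apo 2, 935 without Mg-Apo 3, 933 without Mg 2 and 850 without Mg 3, and the Mg-Apo count without one of those libraries lay between 22 and 77; fewer libraries raise these counts by construction. With a minimum of 10 in each of the 3 libraries, a level chosen after seeing the data, 96 transcripts were restricted to Mg and 1 to Mg-Apo, and mixed sets held between 1 and 117. With a minimum of 50 there were 16 and 0, and mixed sets reached 24.

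**Figure D3:**
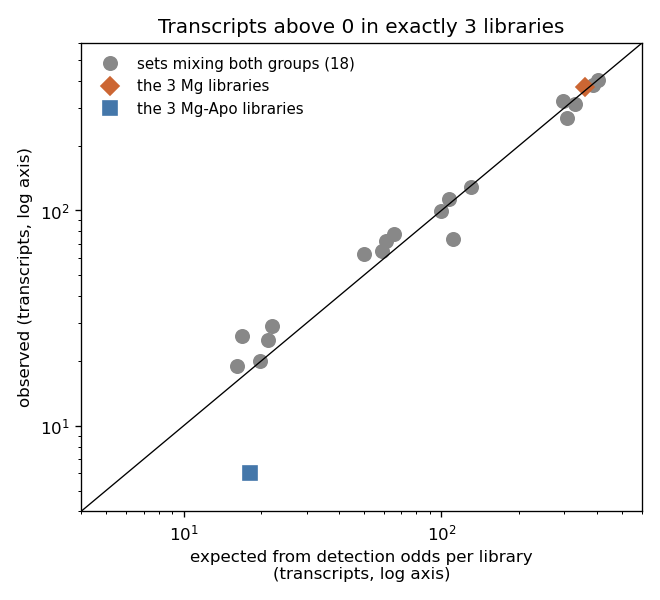
Transcripts above 0 in exactly 3 libraries: the observed number for each of the 20 possible sets of 3 libraries (vertical axis, log scale) against the number expected from a single odds of detection per library (horizontal axis, log scale); the line marks equality. The Mg set has 375 observed and 362 expected, and the Mg-Apo set has 6 observed and 18.0 expected.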

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

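The number of transcripts past the adjusted threshold was 0 in limma's test in both directions under each of the 20 alternatives run, with the lowest adjusted p between 0.12 and 0.98. The counts at an unadjusted p under 0.05 ran from 97, with detection required in all 6 libraries, to 651, without Mg-Apo 3. The share of these that were higher in Mg was 91.3% in the main test, 59.4% with quantile normalization, 70.1% with detection in all 6 libraries, 78.6% without Mg-Apo 1, 77.0% with Mg 3 as the only Mg library and 46.1% without Mg-Apo 1 and Mg 1; in the test with Mg 3 alone, that library is assumed to vary like the Mg-Apo libraries. With the replicate number as a block there were 0 calls and 442 transcripts at an unadjusted p under 0.05, and the block changed no call. Deviations from the group means correlated at -0.03, 0.07 and -0.02 between the libraries that share replicate numbers 1, 2 and 3. Across groups, the best partners were Mg-Apo 1 with Mg 3, Mg-Apo 2 with Mg 2, and Mg-Apo 3 with Mg 1. Among libraries that share a number, only those numbered 2 were thus best partners. Deviations sum to 0 within each group of 3, so these correlations cannot settle whether the numbers mark pairs. Summing transcripts per gene, chosen after seeing the data, gave 0 calls among 7887 features. The 4 named transcripts kept their direction under every alternative in which they were tested, and none passed the threshold, with limma adjusted p between 0.13 and 0.98. They were picked by smallest p from the same libraries and one group was near 0, so their direction could hardly reverse. The difference in detected transcripts kept its direction with thresholds of 1 (2657) and 10 (1782) and with each library left out (1428 to 4168). The transcripts restricted to Mg numbered 96 at a minimum of 10, 16 at a minimum of 50 and between 472 and 935 when a library was left out, and those restricted to Mg-Apo 1, 0 and between 22 and 163; higher minimums and fewer libraries change these counts by construction. The alternatives with DESeq2 were not run because the values are not counts, and the gene list alternatives were not run because the lists matched 0 genes. The unknown sequencing depth leaves open whether a transcript listed at 0 was absent or missed.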

Other observations

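The tests of the restricted transcripts and of the overall shift were written down before their results were seen. The libraries left out in the tests of the shift were chosen after their numbers of detected transcripts were seen. The test of admixed cells was chosen after its values were seen. The transcripts XR_002334654.1 and XR_002334655.1, singled out after their values were seen, belong to the long non-coding RNA genes LOC110239352 and LOC110239353, which the gene table of Aiptasia genome 1.1 lists next to each other. XR_002334654.1 was at 12270 ± 3873 in Mg and 8414 ± 1032 in Mg-Apo (SD, n = 3 each; exact permutation p = 0.3), and it ranked among the 10 highest means. XM_021048621.1 (LOC110242610, protein coding), also singled out after its values were seen, was at 21689 in Mg-Apo 1 and between 3236 and 4048 in the other 5 libraries. The transcript with at least 10 in each Mg-Apo library that was listed at 0 in Mg, XM_021036152.1 (LOC110231167, protein coding), was at 90.3, 56.6 and 29.4 in Mg-Apo 1, 2 and 3.

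Fitted changes leaned towards higher values in the Mg libraries, but some splits of the 6 libraries that mixed the groups leaned further. The median difference from the remaining libraries was 0.89 for Mg-Apo 1, Mg-Apo 2 and Mg 2 as the lower side. It was 0.88 for Mg-Apo 1, Mg-Apo 2 and Mg 3, and 0.78 for Mg-Apo 1, Mg 2 and Mg 3. The remaining mixed splits gave 0.24 to 0.66. The low number of transcripts in Mg-Apo 1 predicted that the median change of 0.76 would fall below 50% of that without this library, and it fell to 0.15. The high number in Mg 1 made the same prediction, and the median without Mg 1 was 0.55, which argues against it as the whole cause. Mg-Apo 1 stayed in that comparison, so a part played by Mg 1 is left open. Low detection in Mg-Apo 1 is therefore a candidate explanation, but 55.9% of the tested transcripts were listed at 0 there. Leaving that library out would lower the median whatever the reason for those zeros. A general effect of the alga was tested in the 4 libraries of similar detection, where the median was -0.00095, but leaving out the Mg-Apo library with the fewest and the Mg library with the most transcripts removes the difference itself, so the bound set beforehand decides nothing and this effect stays open, as does cell number.

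A second pattern is the 375 transcripts restricted to the alga-containing libraries. If only the libraries' odds of detection mattered, 362 would be expected, a ratio of 1.04. The 18 sets that mix the groups had ratios between 0.66 and 1.54, and 10 of them were at least as high as the Mg set. The ratio of 1.54 came from a set with 16.8 expected. Mixed sets of a size nearer to the Mg set, with 296 to 404 expected, had ratios between 0.87 and 1.09. Detection rates alone could therefore give a count of this size. The odds were fitted to the same libraries, so a general rise in detection in the Mg libraries would be part of the expected number. The model cannot say why detection differed. Assignment of the signal to another transcript of the same gene in aposymbiotic cells has little room in the deposited table: of the 278 restricted transcripts matched to a gene, 219 had no other matched transcript of that gene. Among the 59 that had one, it was above 0 in at least 2 Mg-Apo libraries for 17, which is 28.8% of the 59 and 6.12% of the 278. It is not excluded, because 97 restricted transcripts and 6067 accessions of the whole table matched no gene, and because the few genes with another matched transcript keep the share below the bound set beforehand. The 6 transcripts restricted to Mg-Apo were fewer than the 18.0 expected, a ratio of 0.33 that lies below all 18 mixed sets; its cause was not tested.

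Another hypothesis was that the aposymbiotic cell in Mg 1 and Mg 2 may draw those libraries towards the aposymbiotic group. The mean correlation with Mg-Apo libraries minus that with the other Mg libraries was -0.013 in Mg 1, -0.033 in Mg 2 and -0.0296 in Mg 3, which holds no aposymbiotic cell. Mg 3 was not the lowest, but a single library without such a cell leaves the question open.

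In limma's test, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 calls, 0 higher and 0 lower, and the highest of the others also gave 0, so 10 of 10 splits gave as many. Any split gives at least 0 calls, so this comparison of calls decides nothing. At an unadjusted p under 0.05 the real split gave 503 transcripts and the highest of the others 654, and 5 of the 10 splits gave at least as many as the real one.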
